A study of Mus musculus with 8 samples.

How the data were processed

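RNA was measured in 8 libraries described as mouse CD8+ T cells from B16 tumours, 4 from floxed Plpp1 controls and 4 from Lck-Cre floxed Plpp1 knockouts. Cells were isolated with beads against CD8a on day 14, per the series text. RNA was extracted with TRIzol and made into stranded polyA libraries with a KC-Digital kit, per the labels' protocols. Reads were trimmed with Trimmomatic 0.36 and counted with featureCounts of Subread 1.5.1 on GRCm38, per the submitters' processing notes. The aligner, the annotation release, the strand setting and any use of molecular tags are not given in the sources used here.

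The deposited table holds raw read counts per gene as the authors made them, with gene names, exon coordinates and lengths, and no normalization. All of its 49492 rows name a gene. Its columns carry the sample titles, which give the genotype and a number from 1 to 4. Total counts per library ran from 44118131 to 61999941, so 3 counts, the floor used for a gene at 0, were worth 0.0487 to 0.0691 CPM, or 6 counts and 0.0974 to 0.138 CPM where each mate of 3 read pairs was counted. Such floors cover counting error only.

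Properties of the counting were read from the values. Among genes with 1 to 10 counts, 85.7% to 87.7% of the counts in a library were even, so each mate of a pair appears to have been counted. Genes lying within exons of an abundant gene held counts at a median of 0.482 of its density per base on the opposite strand (105 genes, quartiles 0.112 and 1.82) and 0.257 on the same strand (96 genes, quartiles 0.065 and 1.15). Of these, 26 and 33 lay below 0.1 of the host density, and reads of their own also count. Many such genes thus hold counts at a density like that of their host on either strand, while others do not, so the rule for reads in shared exons stays open and overlapping or antisense genes are uncertain. GENCODE M21, on the same build, supplied transcript sequences for GC content only.

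Counts were tested in edgeR 4.0.16 under R 4.3.3 with limma 3.58.1. Genes were kept by filterByExpr, which left 17940, and libraries were scaled by TMM. The quasi-likelihood F test with robust dispersion compared 4 knockout with 4 control libraries, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Where a group holds few counts, such a value can fall below counting error and understate the uncertainty. CPM values use TMM-scaled library sizes, and means carry SDs over 4 libraries. The biological coefficient of variation was 0.0627.

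Gene lists, 42 in all, were fixed before the data were examined. They comprised 17 pathways, 10 T cell states, 12 sets of markers for other cells and 3 sets for sample quality, and 1295 of their 1301 symbols matched the table. Lists with at least 5 tested members were compared with all other genes by camera on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera called 25 lists, 19 upward and 6 downward, and 12 of the 25 held with an estimated correlation. By kind, 5 of 12 called pathways, 6 of 8 T cell states, 0 of 3 other-cell lists and 1 of 2 quality lists held. Median, mean and test had the same sign in every list. A list member "adjusted over the list alone" was adjusted by Benjamini-Hochberg over the members of its list.

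The rule for named genes was also fixed before the data were examined. It took Plpp1, then the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean CPM is at least 1, leaving out predicted genes, pseudogenes and receptor segments. It added up to 4 called members with the smallest adjusted p of each pathway or T cell list, and the 2 most abundant members of each other list. It gave 147 genes, some of which are not reported here. Other genes are named as chosen after their values were seen, which holds too for the Plpp1 relatives, the X-linked genes, the pigment genes, Lyz2, Cd4 and Cd8a.

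Library pairs were compared before averaging, on halved counts and genes with at least 100 counts. The median chi-square per gene was 1.61 to 3.90 times sampling noise within a genotype (12 pairs) and 22.7 to 31 times between genotypes (16 pairs), so no library was treated as a repeat of another. The first principal component of log2 CPM held 72.8% of the variance and parted the genotypes.

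The fit was tested on simulated counts with the real means and library sizes. Few of the 17743 genes tested there were changed, both up and down, against 64.3% of genes called in the data. The simulation therefore does not test scaling under so broad a difference. The fit recovered 67% of 100 genes changed 1.5-fold and 81.8% of 99 genes changed 2-fold, with 5.13% of calls false. With each read pair counted as 2 counts it recovered 58.8% and 83.7%, with 4.14% false. Camera called the list that had been moved and 0 of 41 others. The simulated genes were drawn independently, while estimated correlations within lists reached 0.55 in the data. This result therefore does not test the preset correlation of 0.01.

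Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors, library size alone, no low-count filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, a replicate block, each library left out, macrophage and melanoma marker covariates, a test against a 1.5-fold change, and other set tests. Halved counts, removal of a GC and length trend, removal of X and Y genes, removal of genes with overlapping exons, and removal of the members shared by the activation and dissociation-stress lists were chosen after seeing the data. A result was taken as turned where its estimate changed sign, or for a list where either its median or its test did.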

Results

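As the series describes them, the libraries held RNA from CD8+ T cells taken out of subcutaneous tumours on day 14. That source was not tested here, and the pigment genes Tyrp1, Tyr and Mlana had 0 counts in all 8 libraries. The tumours were grown from B16, a mouse melanoma cell line, in mice described as female. The labels named 2 genotypes with 4 libraries each. Control mice carried loxP-flanked alleles of Plpp1, which encodes phospholipid phosphatase 1, an enzyme that removes phosphate from phosphatidic acid and related lipids. Knockout mice carried the same alleles with Lck-Cre, a recombinase expressed in T-lineage cells. The series title links loss of this enzyme to PD-1 signalling and to ferroptosis, a form of cell death driven by iron and peroxidised lipids, and the comparison asks how the transcriptome of such cells differs without it. Total counts per library ran from 49856353 to 61999941 in controls and from 44118131 to 57716522 in knockouts. The labels do not say that libraries of a genotype came from separate animals, so every p-value measures the spread between these libraries, which may be technical.

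Counts assigned to Plpp1 were lower in the knockout libraries and 0 in none of them. The gene spans bases 112800894 to 112867881 of chromosome 13 on the plus strand of GRCm38. It averaged 0.892 ± 0.18 CPM (SD, n = 4) in controls and 0.498 ± 0.14 CPM (SD, n = 4) in knockouts, 55.9% of the control mean. The log2 fold change was -0.84 (SE 0.26, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0064). The controls gave 61, 50, 35 and 62 counts and the knockouts 18, 32, 29 and 19. The CPM ranges of the groups overlapped, since knockout replicate 2 stood at 0.698 and control replicate 3 at 0.677. The deleted exon is not given in the sources used here, and the last 102 exonic bases, 112867780 to 112867881, also belong to the opposite-strand gene Skiv2l2, an RNA helicase at 368 CPM. At its mean density Skiv2l2 would bring 4827 counts in these bases over 8 libraries, where Plpp1 held 306 counts in all. Whether none, some or all of the Plpp1 counts are reads of Skiv2l2 was not resolved by gene counts, so the level left in knockouts cannot be assigned to Plpp1 transcripts. With mean levels of macrophage and melanoma markers as covariates the Plpp1 estimate turned to 0.46 (edgeR quasi-likelihood, adjusted p = 0.90). The melanoma covariate itself was 1.36 in controls and 0.75 in knockouts (mean log2 CPM), so this fit cannot part genotype from it. A call lost or turned with these covariates, here or below, therefore does not show that other cells caused it. Among its relatives, Plpp2 stood at 0.436 ± 0.099 CPM in controls and 0.71 ± 0.21 in knockouts, and Plpp6 at 4.59 ± 0.34 and 3.86 ± 0.17 CPM (SD, n = 4). Plpp5 stood at 1.86 ± 0.30 and 2.01 ± 0.12 CPM, and Plpp3, at 4 to 8 counts per library, at 0.105 ± 0.031 and 0.11 ± 0.029 CPM.

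**Figure D1:**
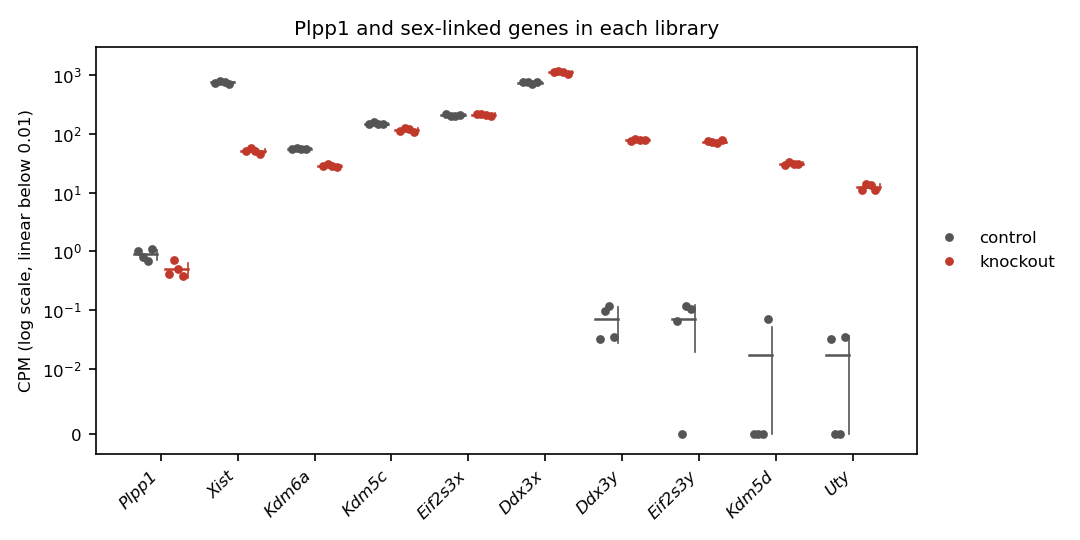
CPM of Plpp1, Xist, 4 X-linked genes and 4 Y-linked genes in each library (vertical axis logarithmic, linear below 0.01 CPM). Points are libraries, horizontal lines the mean of 4 and vertical lines 1 SD. The Y-linked genes lie above 10 CPM in each knockout library and at or below 0.116 CPM in each control library, while Xist falls from 747 to 51.1 CPM.

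Y-linked transcripts were present in the knockout libraries and nearly absent from the controls. Ddx3y, an RNA helicase encoded on the Y chromosome, averaged 78.4 ± 3.1 CPM in knockouts against 0.0703 ± 0.043 in controls (SD, n = 4). The Y-linked translation factor gene Eif2s3y stood at 73.7 ± 3.9 against 0.0715 ± 0.052 CPM. The Y-linked histone demethylase genes Kdm5d and Uty reached 30.9 ± 1.7 and 12.5 ± 1.6 CPM, against 0.0174 ± 0.035 and 0.0169 ± 0.020 (SD, n = 4). Controls held 16, 16, 4 and 4 counts of these genes in all. Xist, the RNA that coats the inactive X chromosome in female cells, fell by 3.87 on the log2 scale (SE 0.060), from 747 ± 27 to 51.1 ± 4.4 CPM, or 6.85% of the control mean. The X-linked partners of these Y-linked genes did not move together. Kdm6a stood at 51.1% of its control mean, Kdm5c at 78.6%, Eif2s3x at 102% and Ddx3x at 150%. The series text describes the mice as female. The 4 Y-linked genes summed to 190 to 203 CPM in the knockout libraries and to at most 0.244 CPM in a control. These values argue against cells of female mice alone as the source of the knockout libraries. How the mismatch with the description arose is not settled. Genotype and sex-chromosome expression therefore changed together in all 8 libraries, and each difference below is also a difference between libraries with and without Y-linked transcripts.

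Across the genome, 11542 of 17940 tested genes (64.3%) differed between the genotypes, 5878 higher and 5664 lower in knockouts (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Past a fitted 2-fold change there were 1040 higher and 1354 lower genes. In 10464 genes (58.3%) the 4 knockout libraries lay wholly above or below the 4 controls, where chance gives 2.86%. Without genes of the X and Y chromosomes, 11159 of 17269 genes passed. The count fell to 3145 when folds were tested against 1.5. It fell to 1099 with the marker covariates, where 45 named genes kept their direction and lost the call, and stood at 7312 of 11406 genes whose exons overlap no other gene.

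Apart from the Y-linked genes, the largest rises included granzymes, the proteases that cytotoxic cells release into their targets. Gzmd rose from 0.246 ± 0.081 to 18.8 ± 0.79 CPM, Gzme from 0.124 ± 0.063 to 7.11 ± 0.69 and Gzmf from 0.648 ± 0.10 to 14.9 ± 2.0 (SD, n = 4). These genes are close paralogs, so reads may be divided among them. Il23a, which encodes the p19 subunit of interleukin-23, rose by 4.92 on the log2 scale, from 0.239 ± 0.098 to 7.37 ± 0.20 CPM (SD, n = 4). Syce1, a gene of the meiotic synaptonemal complex, rose by 6.43, from 0.0837 ± 0.059 to 7.63 ± 1.1 CPM (SD, n = 4). Ankrd33b rose by 4.21, from 0.221 ± 0.077 to 4.17 ± 0.21 CPM (SD, n = 4). Control means of Il23a, Syce1 and Ankrd33b rest on few counts, so the sizes of these rises are imprecise. The largest falls outside Xist and its overlapping antisense gene Tsix (-4.10, SE 0.23) were in genes of low abundance. Slc6a19, a neutral amino acid transporter, fell by 3.48 (SE 0.15) and Spo11, the meiotic break-forming enzyme, by 3.38 (SE 0.23). Kcna2, a voltage-gated potassium channel, fell by 3.28 (SE 0.13), and Dntt, the terminal transferase that adds bases to receptor gene joints, by 3.14 (SE 0.22). Rasgef1a fell by 3.03 (SE 0.16). The pancreatic amylase genes Amy2a2, Amy2a5 and Amy2a3 showed log2 values of -3.97, -3.32 and -3.07, and their near-identical sequences make the split between them uncertain.

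Genes of naive, memory and stem-like T cells were lower in the knockout libraries. Of 41 measured members 37 fell and 4 rose, the same counts as adjusted over the list alone, with a median log2 fold change of -0.89 (camera, adjusted p = 3.0e-11). Tcf7, the transcription factor that maintains stem-like T cells, went from 387 ± 6.7 to 93.3 ± 3.3 CPM (SD, n = 4). S1pr1, which guides exit from lymphoid tissue, fell by 2.27 on the log2 scale (SE 0.052) and the transcription factor gene Myb by 1.53 (SE 0.043). In the list of receptor complex and proximal signalling genes 31 of 45 fell and 8 rose, again as adjusted over the list alone (median -0.30, camera, adjusted p = 7.2e-04). Cd3g, a CD3 chain, fell by 0.77 (SE 0.045) and Plcg1, the phospholipase downstream of the receptor, by 0.63 (SE 0.041). Sh2d1a, an adaptor of SLAM receptors, rose by 0.94 (SE 0.059). Both lists held with an estimated correlation, and both moved in the libraries that carried Y-linked transcripts.

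Interferon response genes were also lower. In the type I list 39 of 48 members fell and 4 rose, as adjusted over the list alone, with a median of -1.07 (camera, adjusted p = 2.9e-11). The DNA-sensor family genes Ifi209 and Ifi203 fell by 2.53 (SE 0.049) and 2.61 (SE 0.051). Slfn1, a Schlafen gene linked to T cell quiescence, fell by 2.03 (SE 0.046). In the list for interferon gamma and antigen presentation 35 of 41 members fell and 3 rose, as adjusted over the list alone, with a median of -0.60 (camera, adjusted p = 3.0e-10). The guanylate-binding proteins, interferon-induced GTPases of host defence, led it. Gbp2 fell by 1.92 (SE 0.047), and Gbp9, Gbp6 and Gbp10, which share exons or reads with neighbouring genes, by 1.92, 1.79 and 2.05. The gene for interferon gamma itself, Ifng, went the other way, from 1.56 ± 0.30 to 25.2 ± 1.2 CPM (SD, n = 4). Both lists held with an estimated correlation.

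Activation, cytotoxic and inhibitory receptor genes were mostly higher in knockouts. Among activation-induced and immediate early genes 30 of 43 rose and 7 fell, as adjusted over the list alone, with a median of 0.62 (camera, adjusted p = 4.5e-06). The heat shock and dissociation-stress list, a possible sign of sample handling, rose too (median 0.89, camera, adjusted p = 1.2e-05), and 12 genes, Atf3 among them, stand in both. Of these 8 rose and 3 fell, and of the 31 other activation genes 22 rose and 4 fell, as adjusted over the list alone (median 0.67, camera, adjusted p = 6.4e-06, chosen after seeing the data). Il2ra, the high-affinity chain of the interleukin-2 receptor, rose from 233 ± 4.2 to 1015 ± 16 CPM (SD, n = 4). Atf3, a stress-induced transcription factor, rose by 3.39 (SE 0.067), and the costimulatory receptor genes Tnfrsf4 and Tnfrsf9 by 2.33 (SE 0.055) and 1.58 (SE 0.045). Of 40 genes of inhibitory receptors and exhaustion 28 rose and 9 fell, or 28 and 10 adjusted over the list alone (median 0.71, camera, adjusted p = 1.2e-04). Tnfrsf4 stands in this list as well as in the activation list, so they are not separate lines of evidence. Lilrb4a, an inhibitory immunoglobulin-like receptor, rose by 2.66 (SE 0.051), and Rbpj, the DNA-binding factor of Notch signalling, by 1.87 (SE 0.052). Ikzf2, the transcription factor Helios, fell by 2.06 (SE 0.057). Members picked after their values were seen did not move together. Pdcd1, which encodes PD-1, rose from 14.5 ± 0.57 to 26.6 ± 1.6 CPM and Havcr2, which encodes TIM-3, from 11.4 ± 0.92 to 51.1 ± 4.0. Lag3 fell from 20.6 ± 0.80 to 13 ± 1.4 CPM, and Tox, a driver of the exhausted state, from 9.46 ± 0.51 to 5.16 ± 0.24 (SD, n = 4).

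In the cytotoxic list 20 of 32 members rose and 6 fell, as adjusted over the list alone, with a median of 0.92 (camera, adjusted p = 3.0e-04), a call lost with an estimated correlation (adjusted p = 0.31). Markers of natural killer and gamma-delta T cells rose with it (median 1.14, camera, adjusted p = 0.0014, and adjusted p = 0.051 with an estimated correlation), and Gzmc stands in both lists. Gzmb, the main apoptosis-inducing granzyme, rose from 906 ± 13 to 4046 ± 247 CPM (SD, n = 4), and Serpinb9, an inhibitor of granzyme B, by 1.95 (SE 0.044). Tissue residency genes gave 12 rises and 4 falls among 22, as adjusted over the list alone (median 0.45, camera, adjusted p = 0.0498, and adjusted p = 0.12 with an estimated correlation), with a median of -0.0029 and adjusted p = 0.35 with the marker covariates. Under 6 other alternatives the call was lost at adjusted p = 0.055 to 0.092, with medians of 0.40 to 0.47. Itgae, the integrin CD103, fell by 2.94 (SE 0.072), while Rgs1, a regulator of chemokine signalling, rose by 2.16 (SE 0.054) and Cish, a cytokine signalling suppressor, by 1.71 (SE 0.044). The residency call ended without control replicate 2 or 3 or knockout replicate 1 or 4, where adjusted p values were 0.0538, 0.056, 0.0657 and 0.0538. The list of short-lived and terminal effector genes was not called (10 rose and 8 fell of 22, as adjusted over the list alone; adjusted p = 0.49). In it S100a4, a calcium-binding protein whose exons overlap a predicted gene, rose by 1.39 (SE 0.068) and Gsap fell by 1.09 (SE 0.054). The effector transcription factors Zeb2 and Id2 rose by 1.24 (SE 0.066) and 1.11 (SE 0.063). Nor was the chemokine list (9 rose and 6 fell of 22, as adjusted over the list alone; adjusted p = 0.39). There Ccl3 and Ccr4 rose by 2.93 (SE 0.10) and 2.05 (SE 0.077), and the homing receptors Cxcr3 and Ccr7 fell by 1.55 (SE 0.066) and 0.96 (SE 0.043).

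**Figure D2:**
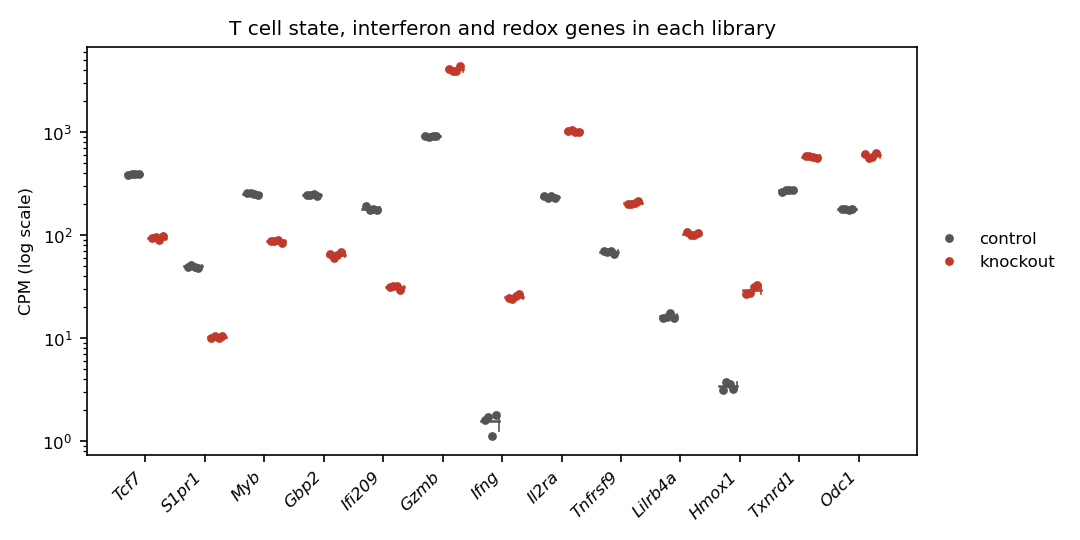
CPM of 13 genes in each library (logarithmic vertical axis). Points are libraries, horizontal lines the mean of 4 and vertical lines 1 SD. Knockout libraries lie below controls for Tcf7, S1pr1, Myb, Gbp2 and Ifi209 and above them for the remaining genes, with Gzmb going from 906 to 4046 CPM.

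Both ferroptosis lists moved upward. They share members with other lists and are not separate lines of evidence. Hmox1 also stands in the NRF2 and iron lists, Ftl1 in the iron list, and Scd1, Cd36 and Agpat3 in lipid lists. Of 32 defence genes 21 rose and 4 fell, as adjusted over the list alone, with a median of 0.48 (camera, adjusted p = 1.3e-04), a call lost with an estimated correlation (adjusted p = 0.15) and with the marker covariates (median 0.26, adjusted p = 0.098). Txnrd1, the cytosolic thioredoxin reductase, rose from 270 ± 5.6 to 575 ± 16 CPM (SD, n = 4). Nqo1, a quinone reductase, rose by 1.17 (SE 0.053), Ftl1, the ferritin light chain, by 1.21 (SE 0.056), and the fatty acid desaturase gene Scd1 by 1.23 (SE 0.060). Gpx4, the peroxidase that reduces lipid peroxides in membranes, stood at 49.7 ± 1.9 CPM in controls and 50.7 ± 4.4 in knockouts (edgeR quasi-likelihood, adjusted p = 0.65). Aifm2, the ubiquinone reductase FSP1, stood at 4.47 ± 0.12 and 4.6 ± 0.14 CPM (adjusted p = 0.72). Both were named after their values were seen. Of 33 genes that promote or mark ferroptosis 20 rose and 7 fell, as adjusted over the list alone (median 0.47, camera, adjusted p = 0.0029), which held with an estimated correlation but not with the marker covariates (median 0.25, adjusted p = 0.051). Hmox1, the haem-degrading enzyme, rose from 3.44 ± 0.29 to 29.5 ± 3.0 CPM and Cd36, a fatty acid scavenger receptor, from 0.465 ± 0.049 to 7.66 ± 0.77 (SD, n = 4). The lysophosphatidate acyltransferase gene Agpat3 rose by 0.80 (SE 0.041), and Dpp4, a surface peptidase, fell by 1.44 (SE 0.044).

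Among glutathione genes and targets of the oxidant-responsive factor NRF2, 27 of 35 rose and 2 fell, as adjusted over the list alone (camera, adjusted p = 4.5e-06, and adjusted p = 0.082 with an estimated correlation). Srxn1, a reductase of oxidised peroxiredoxins, rose by 2.77 (SE 0.088) and the glutathione conjugate exporter Abcc1 by 1.14 (SE 0.045), while Mgst2, a microsomal glutathione transferase, fell by 2.36 (SE 0.051). The iron list was not called (12 rose and 6 fell of 24, as adjusted over the list alone; adjusted p = 0.095), though the metal importer genes Slc39a14 and Slc39a8 rose by 1.04 (SE 0.072) and 0.91 (SE 0.067). These redox and iron genes were measured in libraries that also differed in Xist and Y-linked RNA.

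The list of glycerophospholipid enzymes, which holds Plpp1 with kinases, acyltransferases and phospholipases, was not called. Of its 49 measured members 24 rose and 14 fell, as adjusted over the list alone (median 0.14, camera, adjusted p = 0.25). Dgka, the kinase that makes phosphatidic acid from diacylglycerol, fell by 1.52 (SE 0.045), from 349 ± 8.3 to 122 ± 4.6 CPM (SD, n = 4). Pld4 fell by 2.46 (SE 0.15), and the acyltransferase gene Agpat5 rose by 0.96 (SE 0.062). Genes of unsaturated fatty acid synthesis gave 16 rises and 8 falls among 28, as adjusted over the list alone (median 0.39, camera, adjusted p = 0.033, and adjusted p = 0.12 with an estimated correlation). This call was also lost with the marker covariates (median 0.55, adjusted p = 0.090), without X and Y genes (median 0.36, adjusted p = 0.061) and without genes of overlapping exons (median 0.39, adjusted p = 0.11). Acsl4, which activates polyunsaturated fatty acids for insertion into phospholipids, rose by 0.77 (SE 0.044), Hsd17b12 by 1.2 (SE 0.049) and the elongase gene Elovl1 by 0.75 (SE 0.054). Fatty acid uptake and oxidation was not called (12 rose and 5 fell of 35, or 11 and 5 adjusted over the list alone; adjusted p = 0.38). In it the carrier gene Fabp5 rose by 0.95 (SE 0.048), Cpt1a, which admits fatty acids to mitochondria, fell by 0.54 (SE 0.045), and Pparg rose by 2.68 (SE 0.25). Cholesterol synthesis genes rose in 20 of 25 cases and fell in 1, as adjusted over the list alone (median 0.44, camera, adjusted p = 6.4e-06), and held with an estimated correlation. Cyp51, Idi1, Msmo1 and Acat2 rose by 0.85, 0.91, 0.92 and 0.81.

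Each of the 48 genes of the MYC and ribosome biogenesis list rose, also adjusted over the list alone, with a median of 0.85 (camera, adjusted p = 9.8e-19), which held with an estimated correlation. The polyamine enzymes Odc1 and Srm rose by 1.73 (SE 0.049) and 1.71 (SE 0.050), and the nucleolar factors Nop16 and Rrp9 by 1.35 (SE 0.046) and 1.25 (SE 0.045). Targets of the integrated stress response, the programme set off by amino acid shortage and related stresses, rose in 28 of 35 cases with 0 falls, or 29 adjusted over the list alone (median 0.58, camera, adjusted p = 8.4e-09), and held. The heat shock and dissociation-stress list rose beside this list and the chaperone list below (median 0.89, camera, adjusted p = 1.2e-05), and shares Atf3 with the former. Besides Atf3, Nupr1 rose by 2.36 (SE 0.085), the arginine transporter gene Slc7a1 by 1.18 (SE 0.049) and the mitochondrial folate enzyme Mthfd2 by 1.02 (SE 0.043). Endoplasmic reticulum chaperones gave 22 rises and 1 fall among 30, as adjusted over the list alone (median 0.34, camera, adjusted p = 7.7e-05, and adjusted p = 0.059 with an estimated correlation), and the marker covariates gave a median of 0.31 and adjusted p = 0.11. Hspa5, the chaperone BiP, rose by 0.72 (SE 0.046), Hyou1 by 0.63 (SE 0.043), Manf by 0.74 (SE 0.047) and the transcription factor gene Xbp1 by 0.76 (SE 0.046).

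Glycolysis genes rose in 15 of 25 cases and fell in 4, as adjusted over the list alone (median 0.26, camera, adjusted p = 0.006, and adjusted p = 0.20 with an estimated correlation), a call also lost with the marker covariates (median 0.16, adjusted p = 0.087) and without genes of overlapping exons (median 0.27, adjusted p = 0.061). Hk2, an inducible hexokinase, rose from 40.2 ± 1.5 to 189 ± 13 CPM (SD, n = 4). Pgam1 rose by 0.94 (SE 0.047) and the glucose transporter gene Slc2a1 by 0.88 (SE 0.049). Pdk1, which restrains pyruvate oxidation in mitochondria, fell by 0.67 (SE 0.045). For oxidative phosphorylation 52 of 76 rose and 5 fell, or 53 and 5 adjusted over the list alone (median 0.23, camera, adjusted p = 7.1e-05, and adjusted p = 0.45 with an estimated correlation). With the marker covariates its median was -0.073 (adjusted p = 0.11). Cytochrome c, Cycs, rose by 0.73 (SE 0.056), and Ndufab1, Atp5g1 and Atp5b by 0.77, 0.65 and 0.51. With the marker covariates none of the 4 was called, and Ndufab1 stood at -0.00014 (adjusted p = 0.9998). In mitosis genes 36 of 50 fell and 9 rose, or 36 and 10 adjusted over the list alone (median -0.24, camera, adjusted p = 7.0e-04, and adjusted p = 0.075 with an estimated correlation). The condensin genes Smc4 and Ncapd2 fell by 1.01 (SE 0.047) and 0.67 (SE 0.051) and Nusap1 by 0.64 (SE 0.045), while the mitotic cyclin Ccnb1 rose by 0.57 (SE 0.043). The S phase list was not called (15 rose and 18 fell of 49, as adjusted over the list alone; adjusted p = 0.67). There Orc1, Ccne1 and Exo1 rose by 0.91, 0.43 and 0.44 and Clspn fell by 0.58.

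Targets of p53 gave 20 rises and 5 falls among 27, as adjusted over the list alone (median 0.58, camera, adjusted p = 0.0014), and held with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, rose from 29.4 ± 0.44 to 100.5 ± 4.2 CPM (SD, n = 4) and Tigar by 1.09 (SE 0.052), whereas Trp53inp1 and Sesn1 fell by 1.55 (SE 0.048) and 1.31 (SE 0.055). Apoptosis regulators were not called as a list (19 rose and 14 fell of 41, or 20 and 14 adjusted over the list alone; adjusted p = 0.46). Bcl2l1, the survival protein BCL-XL, rose by 1.93 (SE 0.049), and Bcl2l11, the death-promoting protein BIM, fell by 1.55 (SE 0.054). The death receptor gene Tnfrsf10b rose by 1.42 (SE 0.070).

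**Figure D3:**
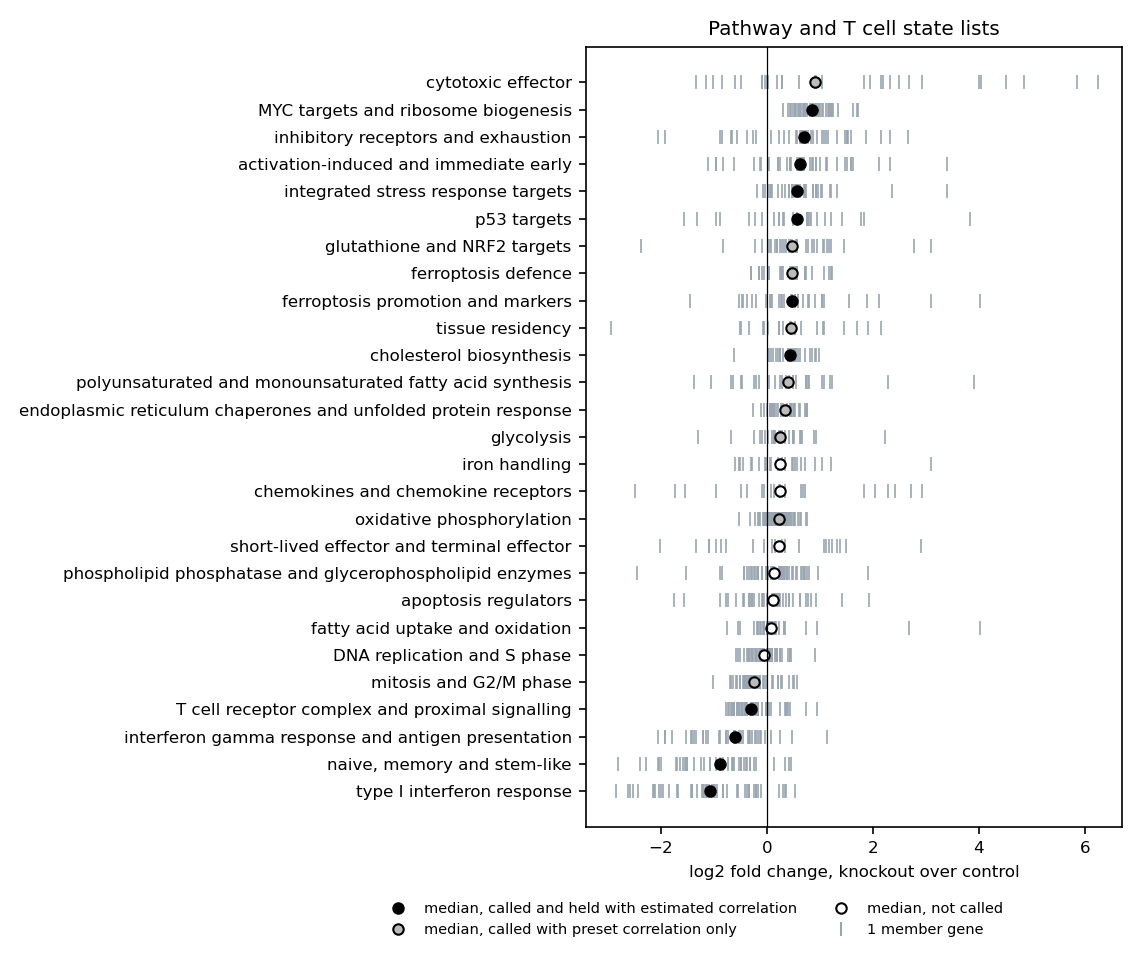
Log2 fold change, knockout over control, of each tested member (ticks) of the 27 pathway and T cell state lists, with list medians as circles. Black circles mark lists called by camera that held with an estimated correlation, grey circles calls lost with it and white circles lists not called. Medians run from -1.07 for the type I interferon response to 0.92 for cytotoxic effectors.

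Markers of other cells ranged from undetected to abundant. Summed CPM of several lists rested on 1 or 2 genes, and these sums were not tested. B cell markers summed to 212 CPM in controls and 108 in knockouts, but to 20.02 ± 0.70 and 15.3 ± 0.38 without Ighm and Igkc (SD, n = 4). Dendritic cell markers summed to 350 and 728 CPM, but to 181 ± 5.2 and 169.9 ± 5.8 without Batf3 and Irf8. Endothelial markers summed to 157 and 90.1 CPM, but to 15.9 ± 0.40 and 21.3 ± 0.89 without Pecam1 and Ramp2. Macrophage markers summed to 176 and 140.4 CPM, and to 97.9 ± 1.3 and 69.3 ± 1.7 without Ctsb and Ctss (SD, n = 4). Among genes chosen after their values were seen, the pigment genes Tyrp1, Tyr and Mlana had 0 counts in all 8 libraries, which allows up to 0.138 CPM in the shallowest if mates were counted singly (6 counts), and the myeloid lysozyme gene Lyz2 stood at 0.629 ± 0.16 CPM in controls and 0.733 ± 0.26 in knockouts (SD, n = 4). Cd8a averaged 331 ± 5.4 and 239 ± 7.8 CPM, and Cd4 2.32 ± 0.16 and 1.52 ± 0.096. Natural killer and gamma-delta T cell markers rose in 15 of 24 cases and fell in 2, as adjusted over the list alone (median 1.14, camera, adjusted p = 0.0014, and adjusted p = 0.051 with an estimated correlation). Gzmc rose by 2.33 (SE 0.058) and the T-box factor gene Eomes by 0.83 (SE 0.058), both also used by CD8+ T cells. The lists for erythroid cells and platelets (10 rose and 2 fell of 15) and for CD4 and regulatory T cells (8 rose and 2 fell of 18) were called at camera adjusted p = 0.023 and 0.049, both as adjusted over the list alone. With an estimated correlation these became adjusted p = 0.13 and 0.12, and the erythroid call also ended with the marker covariates (median 0.85, adjusted p = 0.18, against a median of 1.15) and in 3 other alternatives (medians 1.12 to 1.15, adjusted p = 0.060 to 0.31). Itgb3 fell by 0.90 (SE 0.047), Bpgm stood at 16.8 ± 0.54 and 17.6 ± 0.60 CPM, and Ctla4 at 477 ± 7.0 and 502 ± 26 (SD, n = 4). The activation gene Il2ra is the other leading member of the list for CD4 and regulatory T cells, which summed to 887 CPM in controls and 1816 in knockouts, but to 177 ± 1.8 and 299.5 ± 9.6 without Il2ra and Ctla4 (SD, n = 4). The call for CD4 and regulatory cells ended without knockout replicate 3 (adjusted p = 0.0734) or 4 (adjusted p = 0.0543), and under 3 other alternatives (medians 0.32 to 1.02 against 0.74, adjusted p = 0.074 to 0.096).

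The other marker lists were not called. Melanoma markers gave 3 rises and 6 falls among 11 (median -0.52, adjusted p = 0.11), led by Kit, which fell by 2.33 (SE 0.079), and by Pmel (-1.96, SE 0.081), of which 98 exonic bases overlap Dgka on the other strand. At its mean density Dgka, which also fell, would bring 3658 counts there over 8 libraries, where Pmel held 4763 in all. How many Pmel counts are reads of Dgka was not resolved. Macrophage markers gave 7 and 4 of 22 (adjusted p = 0.77), with Ctss lower by -0.43 (SE 0.053) and Ctsb at 0.12 (SE 0.048), or -0.15 with the marker covariates. Dendritic cell markers gave 11 and 7 of 23 (adjusted p = 0.49), and both leading members are transcription factors that T cells also use. Batf3 rose from 30.4 ± 2.8 to 256 ± 9.6 CPM and Irf8 from 138 ± 4.5 to 302 ± 28 (SD, n = 4). B cell markers gave 5 rises and 7 falls among 20, or 4 and 7 adjusted over the list alone (adjusted p = 0.47). Ighm fell by 1.08 (SE 0.046), and Igkc stood at 4.44 ± 0.43 and 3.78 ± 0.53 CPM. Mast cell and basophil markers gave 5 and 1 of 7, or 6 and 1 adjusted over the list alone (adjusted p = 0.080), with Ms4a2 higher by 1.92 (SE 0.13). This list was called without control replicate 1, 3 or 4, at adjusted p = 0.041, 0.0301 and 0.03. Endothelial markers gave 6 and 2 of 10 (adjusted p = 0.38), and Pecam1, which T cells also express, fell by 1.90 (SE 0.056), while Ramp2, whose exons overlap those of Vps25, stood at 0.16 (SE 0.052), or -0.036 with the marker covariates. Fibroblast markers gave 2 and 3 of 8 (adjusted p = 0.94), with the T cell surface gene Thy1 up by 0.48 (SE 0.070) and Pcolce down (-1.55, SE 0.14). Keratinocyte and muscle markers gave 3 and 2 of 10 (adjusted p = 0.80), with Sfn at 0.28 (SE 0.060) and Mylpf at -1.10 (SE 0.070). Neutrophil markers gave 2 and 1 of 5 (adjusted p = 0.74), with the means of Hdc and G0s2 below 1 CPM in both groups. Hdc rose by 0.56 (SE 0.24, edgeR quasi-likelihood, adjusted p = 0.046), and G0s2 was not called. Apart from the B and mast cell lists, the counts of rises and falls were the same adjusted over the list alone.

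Of 3 lists chosen as signs of sample quality, 2 were called. Whether handling or a response within the cells moved them was not tested. Heat shock and dissociation-stress genes rose in 21 of 28 cases and fell in 4, as adjusted over the list alone (median 0.89, camera, adjusted p = 1.2e-05), and held with an estimated correlation. The constitutive chaperone gene Hspa8 rose by 0.42 (SE 0.051) but stood at -0.040 with the marker covariates (adjusted p = 0.95), and Hsp90ab1 stood at 10368 ± 522 and 10889 ± 245 CPM. Mitochondrially encoded genes fell in 11 of 15 cases and rose in 1, as adjusted over the list alone (median -0.28, camera, adjusted p = 0.023, and adjusted p = 0.49 with an estimated correlation), and over genes without exon overlap their median was 0.12 (adjusted p = 0.96). Among them mt-Co1 fell by 0.25 (SE 0.052) and mt-Cytb had a log2 value of -0.02 (SE 0.052). The list of unspliced and nuclear transcripts was not called (6 rose and 2 fell of 10, as adjusted over the list alone; adjusted p = 0.27). In it Malat1 fell by 0.82 (SE 0.11) and Gm42418, which overlaps ribosomal RNA sequence, rose by 0.80 (SE 0.15) but stood at -0.38 with the marker covariates (adjusted p = 0.80).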

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

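The test of the number of genes over other splits was planned, while all other tests in this part were chosen after the result was seen. A gap test for 1 library far from the other 3 of its genotype was run on 386 sets of 4 values, and 22 (5.7%) passed, where chance gives about 1 in 20.

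Among named genes in control libraries, the value standing apart was 0.0696 CPM for Kdm5d in replicate 4, against 0 in the rest, and 3.80 CPM for Amy2a5 in replicate 2. It was 7.68 CPM for Slc39a14 and 7.66 CPM for Tnfrsf10b, both in replicate 2. In replicate 3 it was 133 CPM for Hyou1, 114 CPM for Cycs and 773 CPM for Thy1, the last against 980 to 1004 CPM in the others. In replicate 4 it was 94.4 CPM for Nop16. In knockout libraries, replicate 1 stood apart with 0.507 CPM for Amy2a5, 0.668 CPM for Amy2a3 and 14.4 CPM for Nupr1. Replicate 2 did so with 20.8 CPM for Scd1 and replicate 3 with 18.4 CPM for Slc39a8. Knockout replicate 4 did so with 234 CPM for Cycs, 89.9 CPM for Gzmc and 1753 CPM for Gm42418, the last against 1112 to 1205 CPM. In that library the most abundant gene, Ncl, took 1.95% of counts, against 2.18% to 2.23% in the others.

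Among list sums, control replicate 1 stood apart with 1598 CPM for inhibitory receptors, and control replicate 3 with 782 CPM for fibroblast markers, a sum that follows Thy1. Knockout replicate 3 did so with 72.9 CPM for erythroid markers. Knockout replicate 4 did so with 1440 CPM for iron handling and 3577 CPM for unspliced and nuclear transcripts, a sum that includes Gm42418.

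A pattern in all 8 libraries is the presence of Y-linked transcripts and the low Xist in knockouts, although the mice are described as female. Reads of X-linked partner genes assigned to their Y-linked copies are argued against, since Y-linked CPM was 0.0153% of partner CPM in controls and 13.3% in knockouts. B16 melanoma cells, from a line founded in a male mouse, are argued against by the pigment genes Tyrp1, Tyr, Mlana and Dct, which summed to 0 CPM in each knockout library. Male knockout animals, or knockout libraries from animals other than those the labels describe, stay open and were not tested, since the values that bear on them are those that raised the question. Whether sex contributes to the other differences was not tested, because no library has the genotype without the sex-linked difference, and Xist at 6.85% of controls had no male library to be set against.

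Libraries of a genotype differed little. Deposition of one library several times is argued against, since the median chi-square per gene was at least 1.61 times sampling noise in each pair of a genotype. If each library came from 1 animal with its own T cell clones, receptor variable segments could vary more between libraries than other genes of like abundance. Over 9 segments of at least 10 mean CPM, their spread beyond counting noise was 1.40 times that of 434 matched genes, with a 95% bootstrap interval of 0 to 1.88, which leaves this open. Separate animals, pooled animals and portions of 1 cell pool therefore cannot be told apart.

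For the number of genes called, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes. The real split gave 11542 genes and the highest of the other splits 0. In every other split the genotype difference enters the spread within the groups, so few calls there follow from the design. The real split ranked first, but 35 splits allow no share below 1 of 35, so a chance split is not excluded. For lists called by camera at the preset correlation, 1 of the 35 splits, the real one, gave as many, but the margin was small (25 lists, and 24 in the highest other split). The 16 splits with 3 libraries of a genotype on a side called 15 to 24 lists and the 18 even splits 0 to 2, so such calls also arose where the genotypes were partly mixed. With an estimated correlation the real split called 12 lists and the highest other 0, a comparison with the same limit. A GC content or gene length trend is argued against as the whole cause, since 93.2% of calls among genes with a known GC content were kept after its removal. The 2 groups may still differ in handling or batch as well as genotype, and the labels name no batch.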

How the results depend on the processing

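Halved counts, GC and length correction, removal of X and Y genes, of overlapping genes and of members shared by 2 lists were chosen after seeing the data. The count of differing genes stayed between 10253 and 11828 in 19 alternatives, and between 11010 and 11556 with a library left out. Scaling moved the median of all genes to between -0.043 and -0.013 on the log2 scale. Each scaling gives relative abundance, so none of them can detect a change in total RNA per cell. Plpp1 kept its direction and call in 18 alternatives (log2 -1.04 to -0.73, edgeR, DESeq2 or limma adjusted p = 0.0019 to 0.026). It turned with the marker covariates. The filter of at least 1 CPM in 4 libraries and the removal of overlapping genes left Plpp1 out. Its overlap with Skiv2l2 was therefore not tested by that removal. Named genes other than Plpp1 gave 3015 values, of which 2932 kept direction and call, 66 lost the call, 4 gained it and 13 turned. The 25 called lists gave 627 values, of which 582 held, 42 lost the call and 3 turned, and the 17 others 419, of which 40 gained a call and 29 turned. Depth limits genes near the floor, such as Plpp1 at 98 counts over the knockouts.

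With the replicate block 11516 genes, 25 lists and 3 other-cell lists were called, and Plpp1 stood at -0.84. Of its values, 1 lost its call (Hdc). Deviations of same-numbered libraries correlated at 0.0049, 0.057, 0.022 and 0.020 over all tested genes, and at 0.11, 0.23, -0.086 and 0.18 over genes above a mean log2 CPM of 3. In the first set 3 of 8 libraries, and in the second 4 of 8, correlated best with their own number.

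Marker covariates called 1099 genes (600 higher, 499 lower) and 17 lists, against 25, and ended the call of 45 named genes and 6 lists besides those that turned. The melanoma covariate itself differed between groups (1.36 against 0.75 mean log2 CPM), so this fit cannot part genotype from it, and the cause was not tested. Under them Plpp1 turned to 0.46, and Ndufab1 to -0.00014, Ctsb to -0.15, Ctla4 to -0.31, Ramp2 to -0.036, Bpgm to -0.093, Hsp90ab1 to -0.16, Hspa8 to -0.040 and Gm42418 to -0.38. List medians were -0.073 for oxidative phosphorylation, 0.078 for apoptosis (its test turned), -0.0029 for tissue residency, 0.29 for melanoma, -0.044 for macrophage, -0.20 for dendritic cell, -0.90 for neutrophil and 0.096 for fibroblast markers. Genes without exon overlap gave 7312 calls (3693 higher, 3619 lower) because fewer genes were tested, and medians of -0.043 for apoptosis, 0.11 for fibroblast, 0.0088 for keratinocyte and 0.12 for mitochondrially encoded genes. GC and length correction turned Ctla4 to -0.070, Bpgm to -0.0022 and Hsp90ab1 to -0.021. Testing against 1.5-fold gave 3145 calls (1516 higher, 1629 lower), a stricter question.

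Camera with an estimated correlation called 12 lists and 0 other-cell lists, fry 39 and 10, and mixed fry, which takes either direction, 42 and 12. Fry asks whether members change at all, while camera asks whether they change more than other genes. Since 64.3% of all tested genes were called, the counts of fry are not comparable with those of camera. The directional fry test turned macrophage (median 0.094) and fibroblast markers (median -0.16). It called the macrophage list downward (fry, adjusted p = 8.3e-04) and did not call the fibroblast list (fry, adjusted p = 0.72). Without a filter B cell markers stood at 0.061 and keratinocyte markers at 0.23. With at least 1 CPM chemokines stood at -0.088, macrophage markers at -0.070 and keratinocyte markers at 0.14. In DESeq2 the tests of macrophage (0.093) and endothelial markers (0.46) turned. The fibroblast test turned with upper-quartile factors (-0.19), library size alone (-0.18) and halved counts (-0.18). With a library left out, the ranges were -0.057 to 0.019 for mt-Cytb, -0.14 to 0.20 for B cell, -0.43 to -0.040 for fibroblast and -0.24 to 0.057 for keratinocyte markers. For these the cause was not tested, and none of these lists was called by camera in the reported fit.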

Other observations

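Gene families were looked at after the values were seen, so their tests are descriptive. Of 163 tested segments of the T cell receptor alpha and beta genes, 81 fell and 2 rose (median log2 -0.52, camera, adjusted p = 7.7e-07 over 10 families, and adjusted p = 0.0014 with an estimated correlation). Only 9 variable segments of these genes reached a mean of 10 CPM, and the other variable segments were of lower abundance. Gimap genes, GTPases of lymphocyte survival, fell in 8 of 9 cases (median -0.61, camera, adjusted p = 1.5e-04, and adjusted p = 0.13 with an estimated correlation), and Gimap4 went from 2899 ± 176 to 1250 ± 22 CPM (SD, n = 4). Proteasome subunits rose in 30 of 37 cases and fell in 3 (median 0.33, camera, adjusted p = 1.4e-05, and adjusted p = 0.082 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 13 of 18 cases and fell in 2 (median 0.44, camera, adjusted p = 4.2e-04), a call lost with an estimated correlation (adjusted p = 0.05004). Klr receptors, lectin-like receptors of natural killer and activated T cells, rose in 15 of 20 cases and fell in 2 (median 1.59, camera, adjusted p = 2.9e-04, and adjusted p = 0.082 with an estimated correlation). Schlafen genes fell in 6 of 8 cases and rose in 2 (median -0.90, camera, adjusted p = 0.0099, and adjusted p = 0.082 with an estimated correlation). Cytosolic ribosomal proteins gave 15 rises and 28 falls among 85 (adjusted p = 0.32), and histones 3 and 5 among 30 (adjusted p = 0.82). No family median changed sign under the other scalings.

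Neighbouring genes moved together in a few places. Over 17720 windows of 11 neighbouring tested genes, the median of the mean absolute log2 fold change was 0.49. After the Y chromosome, the highest was 3.23 on chromosome 5, bases 10947805 to 11850352, where 10 of 11 genes rose, nearly all predicted genes of low abundance beside Speer1 (0.179 ± 0.12 to 2.62 ± 0.31 CPM, SD, n = 4). These are near-identical copies, so counts of single members are uncertain. Next came the granzyme and chymase cluster on chromosome 14, bases 55884969 to 56262260 (3.02, 8 genes rose and 2 fell), where the 8 cluster genes tested as a family rose with a median of 3.97 (camera, adjusted p = 1.4e-05), a call lost with an estimated correlation (adjusted p = 0.05004). The window around Xist on the X chromosome, bases 103422010 to 103526330, fell in 11 of 11 genes, many of which overlap Xist. The Klr cluster on chromosome 6, bases 129666015 to 130386874, rose in 10 of 11 genes. The Ifi200 cluster on chromosome 1, bases 173566284 to 174031810, fell in 11 of 11 genes. The family of that name fell in 10 of 11 members and rose in 1 (camera, adjusted p = 2.0e-05, and adjusted p = 0.082 with an estimated correlation). The granzyme and Ifi200 families were chosen after the values were seen, and the windows were ranked by the same fold changes. Gzmb and Gzmd also stand in the cytotoxic list, and Ifi209 and Ifi203 in the type I interferon list. The p-values of these families are therefore descriptive and not separate evidence.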
